A study of Mus musculus with 9 samples.

How the data were processed

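Frozen tissue of 4 wild-type spleens and 5 splenic lymphomas of Sca1-MALT1 transgenic mice gave total RNA that was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The deposited log2 values came from RMA, per the submitters' processing notes; its version, settings and probe definitions are not given in the sources used here. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set, and it compresses differences near the background. The sorted values of the 9 arrays differed by at most 0.149 and their medians lay between 6.88 and 6.97, so the values were used as deposited. The values bore out a log2 scale and no centring of genes.

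The table holds 45101 probe sets, of which 64 Affymetrix controls were kept out of the tests and 45037 were tested. Names came from the platform annotation given for the series: 34958 probe sets had 1 gene symbol, 932 several and 9211 none, and none was named from a probe set with several. The RefSeq gene table of assembly GRCm38.p6 served for names only and changed 0 symbols, and 34741 probe sets had a gene identifier in it. For each of the 18193 genes the probe set with the highest mean over all arrays stood for the gene, and 9010 genes had more than 1.

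Lymphoma and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with no covariate and no filter on dim probe sets. All differences are lymphoma minus wild-type. Of 35 gene lists written out, 34 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, with fry, camera with an estimated correlation and an exact permutation of the list scores as alternatives; the list of sex-linked genes served only as a sample check. Of 544 list members 53 had no probe set of their own here and were not analysed here. Camera called 21 lists (14 higher, 7 lower), fry 3 of these (macrophage, marginal zone and cytokine lists), and camera with an estimated correlation and the exact permutation each called 0, with 3 and 11 lists at an unadjusted p under 0.05. The exact permutation p cannot fall below 0.00794. After adjustment over 34 lists it could call a list only if several lists had p-values near that floor, so its 0 calls say little. Without lymphoma 1 camera called 13 lists. An unequal-variance test called no member of any list. The haematopoietic stem and progenitor list and the interferon-stimulated list had medians and means of opposite sign.

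The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out the sex-linked check genes. In each list it names up to 4 called members, or else the 2 with the largest difference, and it always names 15 genes of interest, 11 of which had a probe set. Further list members given as examples (such as Hmox1, Ccl8 or Gzmb) were chosen after their values were seen. Alternatives were a filter on dim probe sets, another quantile normalization, median centring, an intensity trend or a robust prior, array weights, an unequal-variance test, the replicate number as a block, the Gapdh ratio of each array and the Xist level as covariates, other probe sets per gene, and leaving out each array. On simulated values for the 18193 genes with the pooled SD in both groups, limma recovered 85% of 100 genes changed by a log2 value of 1 and 95% of 100 changed by 2, with 8 false calls. With each group's own SD it recovered 86% and 96% with 24 false calls, or 11.7% of its calls. On the same simulated values the unequal-variance test recovered 66% and 88% with the pooled SD. With each group's own SD it recovered 54% and 82%, with 10 false calls. The simulated genes varied independently of each other, which real genes need not do. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.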

Results

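RNA from frozen spleen tissue was measured on 1-colour Affymetrix mouse arrays, with 1 array per sample. The series holds 5 splenic lymphomas from mice that carry a Sca1-MALT1 transgene and 4 spleens from healthy wild-type mice. MALT1 is a protease and scaffold protein that links antigen receptors to NF-kB, and MALT lymphoma is a B-cell lymphoma of marginal zone type. The comparison asks how expression in the lymphomas of this mouse model differs from that in healthy spleen. The labels number the samples but do not say that they came from separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision of every value below.

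Complement genes were among those that rose in lymphoma. The 3 chains of complement C1q, which spleen macrophages make, rose by log2 values of 2.40 (C1qb), 2.34 (C1qc) and 1.93 (C1qa). Gzmk, a granule protease of cytotoxic T cells, had the largest rise among the called genes, from a log2 level of 7.17 ± 0.48 (SD, n = 4) to 10.17 ± 0.51 (SD, n = 5). Among the genes that fell were Il22ra2, which encodes a secreted receptor that binds IL-22 (log2 difference -2.44), and Marco, a scavenger receptor of marginal zone macrophages (-1.64). The limma adjusted p was 0.00574 for Gzmk, 0.00463 for C1qc, 0.00574 for Il22ra2 and 0.00816 for Marco.

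In all, limma called 130 of 18193 genes at an adjusted p under 0.05, 74 higher and 56 lower in lymphoma, and 52 of them differed at least 2-fold (36 higher, 16 lower). The balance of directions was not stable. At an unadjusted p under 0.05 limma had 1217 genes higher and 1456 lower. Called genes were 83 higher and 99 lower without lymphoma 3, and 236 higher and 92 lower without lymphoma 2. Among the 45037 probe sets, 219 were called (113 higher, 106 lower), 92 of them with at least a 2-fold change (57 higher, 35 lower). The groups did not overlap for 1334 genes, or 7.33% of those measured, where chance gives 1.59%, and all 130 called genes were among them. Of the called genes 74 had more than 1 probe set, of which 9 had a probe set of the opposite sign, none of them called. The number of called genes depended on single arrays: it was 36, 10, 14 and 18 without wild-type spleens 1, 2, 3 and 4, 328 without lymphoma 2 and 34 without lymphoma 5. The 18S control level and the erythroid score as covariates, and leaving out a pair of lymphomas, were chosen after seeing the data. With the 18S level limma called 14 genes and 0 probe sets. Of the 39 called genes that the text names, 6 (C1qa, C1qc, Clec4n, Gzmk, Il22ra2 and Mcoln3) stayed called with any 1 array left out. A test with unequal variances called 0 genes, with 2384 at an unadjusted p under 0.05 against 2673 by limma.

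The other large rises included further genes of macrophages and related myeloid cells. Ms4a6d rose by 2.12, Wfdc17 by 2.21, the lectin receptor gene Clec4n by 1.89, the ficolin gene Fcna by 1.79 and the Fc receptor gene Fcgr3 by 1.64, all on the log2 scale. Fabp4, a fatty acid binding protein of fat cells and macrophages, rose 7.98-fold, the growth factor gene Pdgfc by a log2 value of 1.87 and the platelet and myeloid receptor gene Clec1b by 1.67. The limma adjusted p of these 8 genes lay between 0.00724 and 0.0431. The largest fall among the called genes was that of Snap91 (-2.55), a clathrin adaptor best known from neurons, followed after Il22ra2 by the calcium channel gene Ryr3 (-2.43) and Edaradd (-2.26), an adaptor of the ectodysplasin receptor. Crisp3 (-1.86), Serpinb7 (-1.62), the ion channel gene Mcoln3 (-1.58), Adam23 (-1.47), Kmo (-1.39), an enzyme of tryptophan breakdown, Adgb (-1.34) and Xkrx (-1.30) made up the rest of the 12 largest falls among them. The limma adjusted p of the 12 falls lay between 0.00574 and 0.0415.

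**Figure D1:**
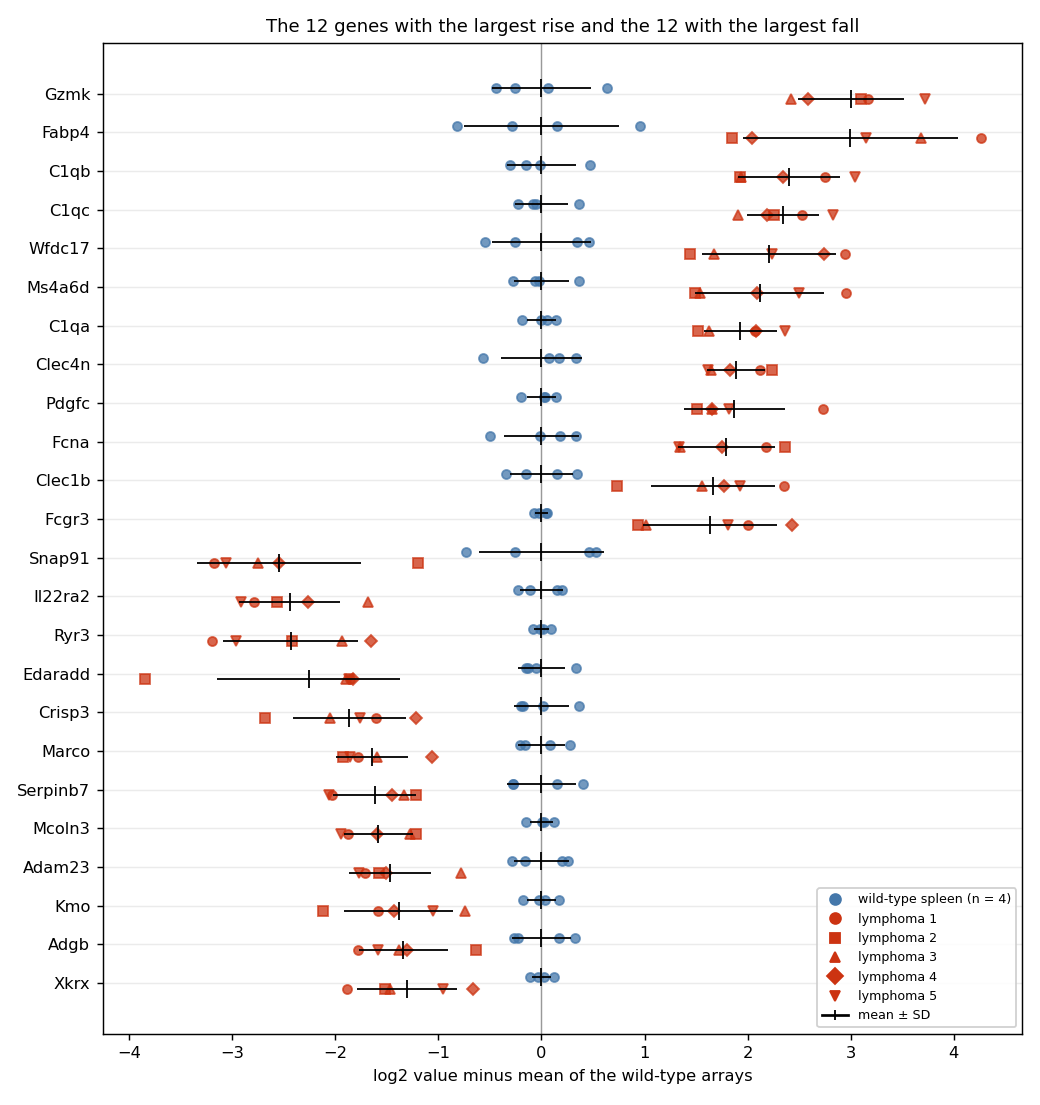
Log2 values of the 12 called genes with the largest rise and the 12 with the largest fall, each array shown relative to the mean of the 4 wild-type arrays (horizontal axis, log2 units); bars give the mean ± SD of each group. No lymphoma array overlaps the wild-type arrays in any of these genes, and lymphoma 2 stands lowest for Edaradd.

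The macrophage and monocyte list rose as a group. Of its 20 measured members 9 rose, 1 fell and 10 did not pass (12 higher and 1 lower adjusted over the list alone). Besides the C1q genes, the risers included Hmox1 (1.63), Spic (1.38) and Slc40a1 (1.21), which serve red pulp macrophages in the recycling of haem iron, and Cd68 (0.996), Axl (0.78) and Vcam1 (0.77). Marco was the member that fell, whereas Csf1r (0.20), Adgre1 (0.49, or 0.27 without lymphoma 1) and Siglec1 (-0.06, or -0.013 without wild-type spleen 4) did not pass. Camera gave the list an adjusted p of 6.88e-13, with an adjusted p = 0.0991 with an estimated correlation, and the fry adjusted p was 0.00337. The list score was higher in all 5 lymphomas than in all 4 wild-type spleens.

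Marginal zone B-cell genes fell. Of 10 measured members 4 fell and 6 did not pass (7 lower adjusted over the list alone): Cd1d1 (-0.98), which presents lipid antigens, the sphingosine phosphate receptor gene S1pr3 (-0.85), Myof (-0.85) and Asb2 (-0.58). The camera adjusted p was 1.30e-07 and the fry adjusted p 0.00296, with an adjusted p = 0.0991 with an estimated correlation. The mature B-cell list was lower too by camera (adjusted p 2.87e-06, but adjusted p = 0.532 with an estimated correlation). None of its 20 members was called by limma (0), with 6 lower at an unadjusted p under 0.05, and 2 lower adjusted over the list alone. Its largest differences were those of the transcription factor gene Bach2 (-0.89, limma adjusted p 0.0531) and Ralgps2 (-0.66, 0.181).

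The follicular B-cell list was also lower by camera (adjusted p 0.0304, adjusted p = 0.532 with an estimated correlation). Of its 5 members limma called 0, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Fcer2a, the low-affinity IgE receptor, at -1.77 and S1pr1 at -0.62. Its call was lost without lymphoma 1 (camera adjusted p 0.103), wild-type spleen 1 (0.0555) or lymphomas 1 and 2 together (0.0893), and with the dim filter (0.075), the 18S level (0.353) or the erythroid score (0.175). MHC class II genes, by which B cells and myeloid cells present antigen, were lower by camera (adjusted p 0.0186, adjusted p = 0.532 with an estimated correlation). Of these 9 genes limma called 0, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with H2-Ob at -0.64 and Ciita, the regulator of the class, at -0.51. The call ended without lymphoma 1 (camera adjusted p 0.0979) or lymphomas 1 and 2 (0.121), and with the dim filter (0.0662) or the erythroid score (0.157). Germinal centre B-cell genes did not pass (camera adjusted p 0.202): limma called 0 of 10, 2 lower at an unadjusted p under 0.05 and 1 lower adjusted over the list alone, with Rgs13 at -1.37 (-0.74 without lymphoma 2) and Mybl1 at -1.17. B-cell precursor genes did not pass either (camera adjusted p 0.646). Of 6 members limma called 0, and 0 were at an unadjusted p under 0.05 or called adjusted over the list alone. The pre-B receptor gene Vpreb1 stood at 0.88 and the recombinase gene Rag1 at 0.79, with SDs of 1.92 and 1.93 among the 5 lymphomas, and at 0.028 and -0.076 without lymphoma 1.

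Genes of antibody secretion were higher by camera. The plasma cell list had a camera adjusted p of 0.0132 (adjusted p = 0.532 with an estimated correlation). Among its 16 members limma called 0, with 5 higher and 1 lower at an unadjusted p under 0.05, and 2 higher adjusted over the list alone. The chaperone gene Creld2 stood at 1.18 and Jchain, which joins IgA and IgM units, at 0.72. Genes of the unfolded protein response, with Sdf2l1 at 0.49 and the chaperone gene Calr at 0.42, had a camera adjusted p of 0.0321 (adjusted p = 0.532 with an estimated correlation), and limma called 0 of 18, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The immunoglobulin list had a camera adjusted p of 0.0174 (adjusted p = 0.532 with an estimated correlation). Among 19 members limma called 0, 3 higher at an unadjusted p under 0.05 and 1 higher adjusted over the list alone, with Igkv6-20 at 1.05 and Igha at 1.04 (limma adjusted p 0.0671). All 3 calls rest on few arrays. Without lymphomas 3 and 5 the camera adjusted p-values of the plasma cell, unfolded protein response and immunoglobulin lists were 0.728, 0.459 and 0.434, and with the Xist level as a covariate 0.805, 0.532 and 0.514. Leaving out 1 array ended the plasma cell call without lymphoma 3 (0.0833) or 5 (0.0715) and the immunoglobulin call without lymphoma 1 (0.0674), 3 (0.0863) or 5 (0.0596). The unfolded protein response call ended without wild-type spleen 4 (0.0814) or lymphoma 1 (0.0678), 2 (0.0763), 3 (0.0833) or 5 (0.139). In other settings the plasma cell call ended with the Gapdh ratio (0.0692) or the erythroid score (0.0533), and the immunoglobulin call without probe sets that may match several transcripts (0.137). The unfolded protein response call ended with the Gapdh ratio (0.0692), the 18S level (0.332), the erythroid score (0.269) or array weights (0.0555), and without lymphomas 1 and 2 (0.181).

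The probe sets filed under the IgM heavy chain gene Ighm disagreed. Of 11 probe sets, 7 spread over 2 log2 units or more among the lymphomas, by 2.21 to 7.08. On the probe set with the widest spread lymphoma 2 lay within the range of the wild-type spleens and the other 4 lymphomas above it. The probe set that stands for the gene, by the highest-mean rule, differed by only 0.36. In lymphomas 3 and 5 it stood at 15.375 and 15.42, the highest value on those arrays, so it had little room to show a larger rise.

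**Figure D2:**
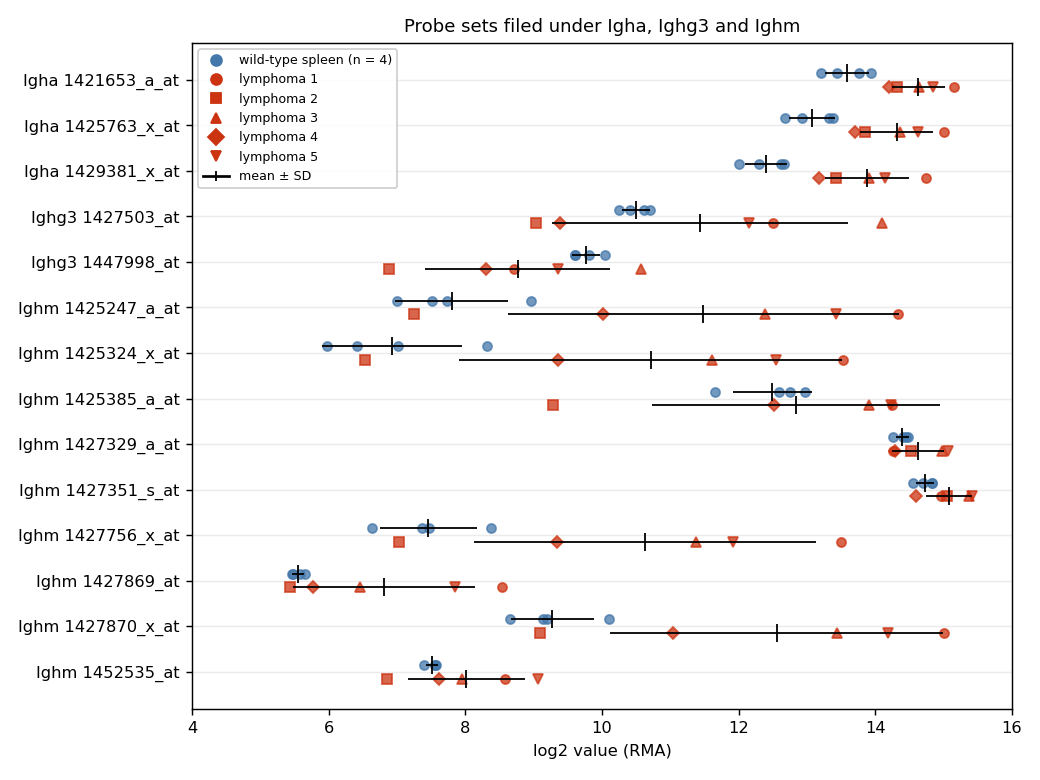
Log2 RMA values (horizontal axis) of probe sets filed under Igha, Ighg3 and Ighm whose lymphoma mean exceeds 6, per array with mean ± SD of each group. The widest Ighm probe set spans 7.08 log2 units among the lymphomas.

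T-cell and cytotoxic lists differed in opposite directions. Of 12 NK and cytotoxic genes 1 rose (Gzmk) and 11 did not pass (5 higher adjusted over the list alone), and the list was higher by camera (adjusted p 0.000363, adjusted p = 0.409 with an estimated correlation). Gzmb (1.17), Eomes (0.74) and Nkg7 (0.64) did not pass. The T-cell list was lower by camera (adjusted p 0.00132, adjusted p = 0.532 with an estimated correlation). Limma called 0 of its 16 members, 3 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, with the CD8 chain genes Cd8b1 at -1.69 and Cd8a at mean levels of 9.23 in lymphoma and 10.23 in wild-type. T-cell scores were -0.91 and -0.97 in lymphomas 1 and 2 and between 0.18 and 0.37 in the others. The list's call was lost with array weights (camera adjusted p 0.0746) and with the erythroid score (0.587). It was also lost without those 2 lymphomas (0.984) and with the 18S level (0.85), and in both camera placed the list higher relative to the other genes. The mean difference of the list without those 2 lymphomas was still negative, at -0.051. Genes of regulatory, follicular helper and checkpoint T cells were higher by camera (adjusted p 0.0325, adjusted p = 0.582 with an estimated correlation). Among 12 members limma called 0, 1 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Il21 at 1.11 (0.66 without lymphoma 5) and Ctla4 at 0.82. With the Xist level as a covariate the list turned lower (camera adjusted p 0.635), and without lymphomas 3 and 5 it did not pass (0.918). Its call was also lost without wild-type spleen 1 (0.0555) or 2 (0.0558) or lymphoma 3 (0.133) or 5 (0.131), with the Gapdh ratio (0.112) and with the dim filter (0.193).

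Cytokine and chemokine genes rose as a group (camera adjusted p 2.15e-06, fry adjusted p 0.00921, adjusted p = 0.0991 with an estimated correlation). Of 22 members 2 rose, the T-cell and monocyte attractant gene Ccl5 (1.08) and Il18 (0.58), and 20 did not pass (7 higher adjusted over the list alone). Ccl8 stood at 2.69 and Il10 at 1.68 without passing. The activated B-cell-like lymphoma list was higher by camera (adjusted p 0.0051, adjusted p = 0.409 with an estimated correlation): of 14 members 1 rose, the ectonucleotidase gene Entpd1 (0.86), and 13 did not pass (3 higher and 1 lower adjusted over the list alone). The list's call was lost with the Xist level as a covariate (camera adjusted p 0.0814) and without lymphomas 3 and 5 (0.0778).

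Genes near the transgene's pathway did not pass. Malt1 differed by -0.59 (limma adjusted p 0.133), and its 3 probe sets were all lower in lymphoma with none called. Whether they read the transgene's transcript is not given in the sources used here, so they check nothing about it. Its partner Bcl10 differed by -0.11 (-0.050 without lymphoma 1), and without probe sets that may match several transcripts by 0.12. Members of the complex and of antigen receptor signalling were lower by camera (adjusted p 0.00134, adjusted p = 0.532 with an estimated correlation); limma called 0 of 15, 4 lower at an unadjusted p under 0.05 and 2 lower adjusted over the list alone, with the kinase gene Btk at -0.42. NF-kB target genes were lower by camera (adjusted p 0.0294, adjusted p = 0.532 with an estimated correlation). Limma called 0 of 23, 1 higher and 6 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Ccr7, which guides lymphocytes to T zones, at -0.91 and the survival gene Bcl2l1 at 0.79 (0.48 without lymphoma 1). Their call was lost without lymphoma 1 (camera adjusted p 0.222), lymphoma 4 (0.0515) or lymphomas 1 and 2 (0.251), and with the dim filter (0.223), array weights (0.104), the 18S level (0.117) or the erythroid score (0.15).

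Among other genes named in advance for lymphoma, limma called none. Bcl6 stood at -0.65, Pax5 at -0.51, Irf4 at -0.27 and Bcl2 at -0.22, the last 2 at -0.096 and -0.020 without lymphoma 1. Prdm1 stood at 0.54, Xbp1 at 0.48 (0.31 without lymphoma 5), the tumour suppressor locus Cdkn2a at 0.42 (limma adjusted p 0.0921), Mki67 at 0.54 and Myc at 0.18. Without lymphoma 1 Mki67 was at 0.099 and without lymphoma 2 Myc at -0.14, and both changed sign without lymphomas 1 and 2, to -0.48 for Mki67 and -0.17 for Myc. With another single array left out Mki67 reached 1.08 and Myc 0.31.

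Blood-forming lineages were higher by camera, with wide spread among lymphomas. All 15 neutrophil and granulocyte precursor genes and all 18 erythroid genes had positive differences, yet limma called 0 of either list (7 and 1 at an unadjusted p under 0.05, 0 and 0 adjusted over the list alone). S100a9 stood at 3.41, Lcn2 at 3.15 (2.07 without lymphoma 1), Rhag at 2.36 and Hbb-b2 at 2.33 (-0.15 where probe sets that may match several transcripts are left out). Camera gave adjusted p-values of 2.15e-06 and 0.000212 (both with an adjusted p = 0.532 with an estimated correlation). Of 12 megakaryocyte and platelet genes 1 rose, Clec1b, and 11 did not pass (1 adjusted over the list alone; camera adjusted p 0.000136, adjusted p = 0.532 with an estimated correlation). Mast cell and basophil genes, with Hdc at 0.46 and Mcpt8 at 0.45 (0.24 and 0.14 without lymphoma 1), had a camera adjusted p of 0.0294 (adjusted p = 0.532 with an estimated correlation), and limma called 0 of 7, none at an unadjusted p under 0.05 or adjusted over the list alone. This call ended without lymphoma 1 (camera adjusted p 0.103), lymphomas 1 and 2 (0.343) or probe sets that may match several transcripts (0.075), and with array weights (0.104), the 18S level (0.318) or the erythroid score (0.459). Without lymphomas 1 and 2 the erythroid difference was 0.082 against 1.497 over all arrays (camera adjusted p 0.822), and without lymphoma 1 the neutrophil difference was 1.18 against 1.92. The erythroid call also ended with array weights (0.0707) and the 18S level (0.583). Erythroid scores were 2.90 and 2.68 in lymphomas 1 and 2, 0.04, -1.72 and -0.57 in lymphomas 3 to 5, and 0.24 in wild-type spleen 1 against -1.17 to -1.21 in the other wild-type spleens.

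Cell cycle genes followed the same arrays. All 19 genes of DNA replication and G1/S had positive differences, and the list was higher by camera (adjusted p 0.0152, adjusted p = 0.607 with an estimated correlation). Limma called 0 of them, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Ccne1 at 0.82 and Cdc6 at 0.69. Without lymphoma 1 or 2 its camera adjusted p was 0.259 or 0.336, and without both the list turned lower (0.00621). It also turned lower with the erythroid score (0.000713) and the 18S level (0.102), and did not pass with array weights (0.744). The G2/M and mitosis list did not pass (camera adjusted p 0.085), but it was called higher in 10 of 26 other settings, among them without wild-type spleen 1 (0.0467) or 3 (0.0488) or lymphoma 3 (0.0491), 4 (8.54e-06) or 5 (0.0472), and turned lower without lymphomas 1 and 2 (0.000307); limma called 0 of 19, none at an unadjusted p under 0.05 or adjusted over the list alone, with Ube2c and Ccna2 both at 0.74. With 1 array left out the values ran from 0.32 to 1.25 for Ube2c and from 0.31 to 1.24 for Ccna2. They ran from 0.47 to 1.19 for Ccne1 and from 0.23 to 1.37 for Cdc6, each lowest without lymphoma 1. G2/M and mitosis scores were 1.58 and 1.37 in lymphomas 1 and 2 and -1.59 in lymphoma 4.

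**Figure D3:**
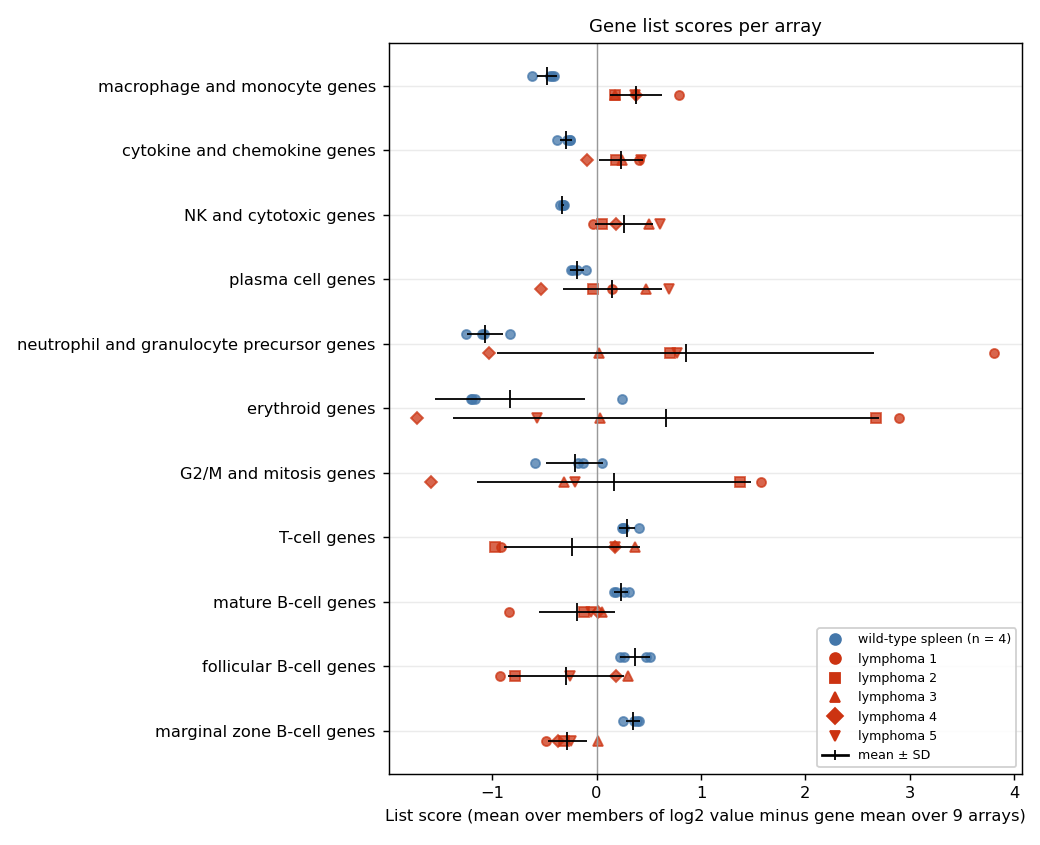
Scores of 11 gene lists per array (horizontal axis, mean over members of the log2 value minus the gene's mean over the 9 arrays), with mean ± SD of each group. Macrophage scores of all lymphomas lie above those of all wild-type spleens and marginal zone scores below them, while erythroid scores of the lymphomas run from -1.72 to 2.90.

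The lymphomas differed more among themselves than the wild-type spleens did. The median SD of a gene was 0.196 among lymphomas and 0.109 among wild-type spleens, a ratio of 1.80, and 78.9% of genes had the higher SD in lymphoma. The mean distance of an array to its group's median profile was 0.346 ± 0.120 (SD, n = 5) against 0.155 ± 0.005 (SD, n = 4), with a two-sided exact permutation p of 0.0238, where the splits of the arrays allow 0.00794 at least. Pairs of wild-type arrays correlated at 0.994 to 0.997 across genes, pairs of lymphomas at 0.956 to 0.989 and pairs across the groups at 0.958 to 0.991. With 1 wild-type spleen left out in turn the exact permutation p was 0.0536. The distances were not computed anew for each split, so these permutation p-values are only approximate as a test of spread.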

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

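Of the tests in this part, those of erythroid content, of mature B-cell content and of weak hybridisation were chosen only after the result was seen. Lymphoma 1 stood apart in several gene groups. It had the highest B-cell precursor score among the lymphomas (1.68, the others -0.44 to -0.18), with Vpreb1 at 10.05 (others 5.61 to 5.91) and Rag1 at 7.86 (3.35 to 3.65). Its mature B-cell (-0.83) and MHC class II (-0.60) scores were the lowest and its adipocyte score (1.04) the highest, with Mcpt8 at 6.98 and Pdgfc at 9.16. Lymphoma 2 had the highest p53 target (0.49) and ribosome biogenesis and MYC target (0.16) scores, with Myc at 11.23 (others 9.44 to 9.84), and the lowest Edaradd (6.79). In other lymphomas Adam23 was highest in lymphoma 3 (7.92), Asb2 in lymphoma 4 (9.76) and Pnliprp1 in lymphoma 5 (4.89), and Mybl1 was lowest in lymphoma 5 (4.77).

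Wild-type spleen 1 had the highest erythroid score of its group (0.24, others -1.21 to -1.17), Hbb-b2 (7.63), Rhag (7.07), Igkv6-20 (6.82) and Rsad2 (9.90). Wild-type spleen 2 had the lowest NK and cytotoxic score (-0.35), Bgn (11.44) and Hmox1 (8.70), and the highest Rag1 (3.83). Wild-type spleen 3 had the lowest Ccl5 (11.63) and the highest Pdk1 (11.57). Wild-type spleen 4 had the highest T-cell (0.40) and mast cell (-0.064) scores and Bbc3 (8.01). Each of these 30 values lay farther from its group than Dixon's gap test allows, out of 282 groups of values tested (10.6%), where chance gives about 1 in 20.

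Control signals outside the comparison lay above those of the wild-type spleens. Y-linked Eif2s3y was at 11.66 and 10.65 in lymphomas 3 and 5 (wild-type 3.90 to 4.01) and at 4.22 in lymphoma 4. Kdm5d was at 5.79 and 5.70 and Uty at 5.93 and 5.35 in lymphomas 3 and 5, where Xist was at 7.92 and 7.15 against 13.85 in the wild-type group. In lymphomas 1, 2 and 4 Xist was at 13.8, 13.91 and 13.69. The labels give no sex, but these signals mark lymphomas 3 and 5 as male and all other arrays as female. Sex is thus partly confounded with group. Calls lost without lymphomas 3 and 5, such as those of the plasma cell and immunoglobulin lists, cannot be told apart from a difference of sex. The 18S signal was 12.68, 13.37, 12.63 and 12.86 in lymphomas 1, 2, 4 and 5 (wild-type 12.15 to 12.37), and the poly-A spike-in 10.09 in lymphoma 4 (8.57 to 9.28).

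Erythroid and cell cycle scores were high in the same lymphomas, 1 and 2. Weak hybridisation of both arrays was argued against through lymphoma 1 alone. Its hybridisation controls, at 11.08, lay inside the range of the other 7 arrays (10.84 to 11.39). Lymphoma 2 lay below that range at 10.47, so weak hybridisation stays open for that array. The values were normalized between arrays, which may hide a weak array. Erythroid precursors divide, so their content may carry the G2/M score: over 9 arrays Pearson's r was 0.927 (permutation p 0.000741, 0.00148 adjusted over 2 relations) and Spearman's rho 0.733 (permutation p 0.0311), but without lymphomas 1 and 2 r was 0.65 (permutation p 0.0925) and rho 0.429 (permutation p 0.354), so the relation rests on those arrays and the explanation stays open. With the erythroid score as a covariate the G2/M list turned lower (camera adjusted p 6.96e-09), which rests on the same arrays, and a first criterion of r above 0.5 alone was met, with the p added to it after the value was seen. Faster division of the lymphoma B cells also stays open: the mature B-cell and G2/M scores had an r of -0.653 (permutation p 0.0689, 0.0689 adjusted over 2 relations) and a rho of -0.383 (permutation p 0.313), and without lymphoma 1 and wild-type spleen 2 an r of -0.222 (permutation p 0.679), so the relation did not pass.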

How the results depend on the processing

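Leaving out 2 lymphomas at a time and the erythroid score and the 18S level as covariates were chosen after seeing the data. The 130 called genes kept their direction in every setting that measured them, except 1 of the 115 measured without probe sets that may match several transcripts. Their groups did not overlap, so leaving out or weighting arrays could not have changed a direction. The unequal-variance test, the trend and the robust prior leave the difference itself unchanged. Only settings that change the values, the probe sets or the covariates could have turned a direction. The dim filter, both normalizations, the trend, the robust prior and the other probe sets per gene kept each count within 1.5 times. The counts of called probe sets, of those with at least 2-fold change and of genes moved in several settings. They were 821, 182 and 532 with array weights, 809, 204 and 459 with the Gapdh ratio as a covariate, 69, 45 and 48 without lymphomas 3 and 5 (Y-linked signal), and 935, 214 and 601 without lymphomas 1 and 2 (high erythroid scores). The unequal-variance test gave 0, 0 and 0 (5463, 331 and 2384 at an unadjusted p under 0.05). With the Xist level as a covariate 111 probe sets and 86 genes were called. The cause was not tested in any of these. With the 18S level as a covariate 0 probe sets, 0 with at least 2-fold change, 14 genes and 17 lists were called (3782, 405 and 1659 probe sets, 2-fold probe sets and genes at an unadjusted p under 0.05). The 130 called genes kept their direction there, with a median size of the difference of 0.844 against 0.84 and a median standard error of 0.167 against 0.13. At the median the differences of these genes were thus not smaller, while their errors were wider. Of the 14 genes called there, 6 were among the 130, and all 14 were higher in lymphoma, so every called fall lost its call. Why single calls ended was not tested. With 1 array left out the counts ran from 0 to 530 probe sets, 0 to 177 with at least 2-fold change (0 without wild-type spleen 2 or 3, where limma had 4191 and 4505 probe sets at an unadjusted p under 0.05), 10 to 328 genes and 13 to 22 lists. With 1 array left out the ratio of spreads ran from 1.59 to 2.06, and with the dim filter it was 2.41. Camera with an estimated correlation called 0 lists, fry 3 and the exact permutation 0. The robust prior does not apply to camera and was not run for lists.

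The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at 0.118, -0.201, 0.141 and 0.004, and 1 number matched best. The fit with the replicate number as a block called 5 probe sets, 5 with at least 2-fold change and 7 genes, and 17 lists. No wild-type spleen shares the number of lymphoma 5, so that array added nothing to the differences in this fit. It ended the camera calls of the follicular B-cell (adjusted p 0.0534), plasma cell (0.0534), immunoglobulin (0.0562), unfolded protein response (0.124) and regulatory T-cell (0.194) lists.

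Of 2635 values of named genes in other settings, 2206 kept sign and call, 340 lost the call, 59 gained one and 30 changed sign. Only 39 of the 107 named genes were called over all arrays. Just these could lose a call, so many of the values that kept theirs belong to genes never called. The changes of sign were in genes that limma did not call, and the cause was not tested. With array weights Mki67 was at -0.022 and Myc at -0.039. Without probe sets that may match several transcripts Bcl10 was at 0.12 and Hbb-b2 at -0.15. With 1 array left out Myc ran from -0.14 (without lymphoma 2) to 0.31 and Rag1 from -0.076 (without lymphoma 1) to 1.05. Without lymphomas 1 and 2 the values were -0.31 for Ccna2, -0.076 for Ccne1, -0.49 for Cdc6, -0.48 for Mki67, -0.17 for Myc, -0.11 for Rag1, -0.29 for Ube2c and -0.020 for Vpreb1. With the erythroid score as a covariate they were -0.35 for Ccna2, -0.046 for Ccne1, -0.57 for Cdc6, -0.56 for Mki67, -0.10 for Myc, -0.053 for Rag1 and -0.32 for Ube2c. With the 18S level as a covariate they were -0.25 for Ccna2, -0.084 for Ccne1, 0.042 for Cd209a, -0.45 for Cdc6, -0.21 for Cdkn1a, -0.24 for Mki67, -0.54 for Myc, 0.17 for Rgs13 and -0.31 for Ube2c.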

Other observations

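Of the tests in this part, the comparison of marginal zone with mature B-cell scores, that of macrophage with other scores and those with the 18S level were chosen only after the result was seen. Several gene groups differed in size between lymphomas. Lymphomas 3 and 5 had the highest NK and cytotoxic scores (0.50 and 0.61, wild-type -0.35 to -0.32), the highest regulatory, follicular helper and checkpoint T-cell scores (0.45 and 0.98) and the highest plasma cell scores (0.47 and 0.70). Lymphoma 1 led in neutrophil (3.80), megakaryocyte (2.03), mast cell (0.72) and haematopoietic stem and progenitor (0.67) scores. Lymphoma 4 had the lowest erythroid (-1.72), G1/S (-0.997) and plasma cell (-0.53) scores. These groupings were seen in the data and were not tested.

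Stromal and other lists did not pass by camera over all arrays, though some did in other settings. The fibroblast and stromal list had a camera adjusted p of 0.0619, with the proteoglycan gene Bgn at 0.89 (limma adjusted p 0.0511) and the pericyte receptor gene Pdgfrb at 0.86. It was called in 10 of 26 other settings, such as the dim filter (0.0199), array weights (0.004), the 18S level (4.66e-06) and without wild-type spleen 3 (0.0356) or 4 (0.0446) or lymphoma 2 (0.0028). The endothelial list (0.187) had the sinusoidal scavenger receptor gene Stab2 at 0.84 and Cldn5 at 0.50 (0.24 without lymphoma 1), and the dendritic cell list (0.109) Cd209a at -0.62 and Siglech at -0.58. The haematopoietic stem and progenitor list (0.304) held Procr, which fell by 0.55 (limma adjusted p 0.0264). The p53 target list (0.0783) had Cdkn1a at 0.94 (0.46 without lymphoma 2) and Bbc3 at 0.61, the interferon-stimulated list (0.425) Rsad2 at 1.83 (1.20 without lymphoma 1) and Gbp2 at 0.76, the ribosome biogenesis and MYC target list (0.0633) Odc1 at 0.46 and Ncl at -0.32, and the glycolysis list (0.29) Pdk1 at -0.64 and Tpi1 at 0.38. Leaving out 1 array also gave calls for the endothelial list (lymphoma 4, 0.0392), the dendritic cell list (lymphoma 3, 0.0399), the p53 target list (wild-type spleen 1, 0.0458, or lymphoma 3, 0.0499) and the ribosome list (wild-type spleen 4, 0.0247, or lymphoma 2, 0.0038). The Xist level as a covariate did so for dendritic cell (0.0145) and p53 target (0.0421) genes, the 18S level for endothelial (0.0115) and ribosome (2.61e-05) genes, and the erythroid score for stem and progenitor (0.0261) and exocrine pancreas (0.0306) genes. The stress list (0.733) held Jun, which rose by 0.78 (limma adjusted p 0.0369). Adipocyte genes were higher by camera (0.0321, adjusted p = 0.532 with an estimated correlation), 1 of 7 having risen (Fabp4, 1 adjusted over the list alone), but not without lymphoma 1 (0.131), wild-type spleen 3 (0.0836), lymphomas 1 and 2 (0.173) or probe sets that may match several transcripts (0.075), nor with array weights (0.116) or the erythroid score (0.213), and exocrine pancreas genes were not (0.129), with Cela1 at 1.38 and Pnliprp1 at 0.20.

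Macrophage genes rose and marginal zone B-cell genes fell, and technical explanations were set against both. A lower share of lymphocytes raises the markers of every other cell type alike, but the macrophage score rose by 0.853 against 0.045 for the mean of the dendritic, endothelial and stromal scores, and it rose above each of the 3 (exact permutation p 0.0159 in all 4 tests). Whether the rise is peculiar to macrophages is open: the mean of 7 other non-lymphocyte scores rose by 0.695 (exact permutation p of the difference 0.69). Its largest parts, the neutrophil, erythroid and megakaryocyte scores, did not pass (exact permutation adjusted p 0.12, 0.335 and 0.286). Macrophage did not pass either (0.0899), although its unadjusted exact permutation p of 0.00794 was the smallest that the splits allow. Without lymphomas 1 and 2 neutrophil (0.984) lay above macrophage (0.783), and erythroid (0.082) and megakaryocyte (0.583) lay below it. A change in the macrophages or in their number stays open, and the mean macrophage difference was 0.869 with the 18S level as a covariate (fry p 0.00229) and 0.923 without lymphomas 3 and 5, so neither accounts for all of it. RNA quality was argued against only as far as 3' over 5' ratios measure it. These ratios are given as log2 values, the 3' level minus the 5' level. The log2 Gapdh ratio differed little between groups (2.24 in lymphoma, 2.32 in wild-type, exact permutation p 0.69), though it was highest in lymphoma 1 (2.80). The log2 beta-actin ratio did not differ either (1.09 and 1.10, exact permutation p 0.88). With the Gapdh ratio as a covariate the difference was 0.899 (fry p 9.53e-05). This met the bound set before the data were examined. The bound was wrong, because a covariate so alike between groups could hardly remove a difference. Other aspects of RNA quality stay open.

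For marginal zone genes the mean difference was -0.633, and -0.743 without lymphomas 3 and 5, which argues against the Y-linked arrays. With the Gapdh ratio as a covariate it was -0.66 (fry p 0.000123). As above, the ratios hardly differed between groups, so RNA quality as they measure it can hardly account for the fall. Its other aspects stay open. The 18S level differed between groups (12.74 in lymphoma, 12.21 in wild-type, exact permutation p 0.0397), and with it as a covariate the mean was -0.509 (fry p 0.00169), so it does not account for all of the fall. A lower share of all B cells may account for the fall: the marginal zone score fell by 0.213 more than the mature B-cell score, with an exact permutation p of 0.175. Without lymphoma 1, whose mature B-cell score was lowest, the excess was -0.323 (exact permutation p 0.0286, the smallest that 70 splits allow). Loss of marginal zone B cells and a lower B-cell share cannot be told apart over all 9 arrays.

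Different B-cell clones were tested through immunoglobulin V probe sets that stand out in 1 lymphoma by 2 log2 units or more. The count was 0 of 21, where 94.8% of matched random sets also gave 0, and the largest gap was 0.778. The bound set before the data were examined, at or under the 95th percentile of matched sets, was met, but it was wrong as a bound, because nearly every random set meets it. The test leaves open whether clones differ.

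Other splits of the 9 arrays into 4 and 5 were fitted the same way, 100 in all with the real one included. Among the drawn splits only the real one gave as many genes (130 against at most 107 in another split). The same held for probe sets (219 against 139) and for probe sets with at least a 2-fold change (92 against 52). The share of drawn splits that reached these counts was thus under the bound of 0.05. As 26 splits were not drawn, chance is not excluded over all splits. For camera's gene lists 4 of the 100 splits, the real one included, gave at least the real 21, and another split gave more, at 22. That share met the bound of under 0.05 only narrowly. As 26 splits were not drawn and camera with an estimated correlation called 0 lists, chance stays open for the number of lists. The exact permutation also called 0 lists, but its smallest p of 0.00794 left it hardly able to call any after adjustment. The split with the most genes set lymphomas 1, 3, 4 and 5 against the wild-type spleens with lymphoma 2.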
